A study of Gallus gallus with 89 samples.

How the data were processed

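Single cells came from grafts of the amniogenic somatopleure of untreated wild-type chick embryos, dissociated with trypsin and passed through a cell strainer. Per the labels' protocols, cells were captured on a Fluidigm C1 array and photographed, cDNA was made with the SMARTer v4 kit, libraries with Nextera XT, and paired ends were read on an Illumina HiSeq instrument. The deposited table holds raw read counts per gene for 89 cells. Per the submitters' processing notes, reads were aligned with HISAT2 2.1.0 to the GRCg6a build and counted with featureCounts, and the settings of either are not given in the sources used here. The protocol has no molecular identifiers, so reads amplified from the same molecule were counted more than once, and intervals and floors cover counting error only.

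The table had 13826 rows, 3 of them spike-in RNAs, which were left out of totals and took 5.99% of all reads. Of the 13823 gene rows, 10452 carried a symbol and 3371 an Ensembl identifier, which took 5.93% of gene reads and could not be paired with symbols here. No pair of cells had identical counts, the highest correlation of log values between cells being 0.734 and the median 0.564. Gene coordinates were not used here, as the gene table at hand was of another build, so the planned ratio of Z-linked to autosomal expression was not run.

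From the deposited counts, CPM was computed over all genes of a cell, and a gene was called detected at 10 CPM or more and at least 1 read. All 89 cells passed the filter of 1000 genes with a read. Clustering used log2(CPM + 1) of genes with reads in at least 3 cells. The 1500 genes with the highest variance above a lowess trend on the mean were taken, after the held-out lists, mitochondrial genes and W-linked genes had been left out. Leiden clustering at resolution 1 (seed 0) ran on shared neighbours among the 10 nearest in 10 principal components. No doublet caller was run on so few cells. The labels name no separate animals, so the pooled tissue is 1 sample. No p-value, standard error or test was therefore computed, and SDs are over cells.

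Marker genes for 10 cell types, gene lists, the size rule and the rule for naming genes in the text were fixed before the data were examined. How markers name a cluster was not fixed, and 5 rules were tried after the data were seen, judged partly on whether the names looked plausible and held under other settings. In the rule kept, a marker leads in a cluster when at least 40% of its cells detect it and its mean log value is above that of all cells. A cluster takes the name of the type with at least 3 leading markers and the highest fraction of its measured markers leading. VIM was left out, as it was from the count of cells with markers of both layers. The cardiomyocyte list was left out too, a choice also made after the data were seen. Of the rules not kept, the first took the most markers detected in at least 50% of cells, without those at 50% or more in every cluster. The second, the evenness rule, instead left out markers spread too evenly over clusters. The others took the highest mean z-score or the most leading markers. The first rule, with the cardiomyocyte list in use, gave a mesoderm-like share of 62.9%. The z-score rule, without that list, gave 11.2%. With the cardiomyocyte list added, the rule kept gave 32.6% and the evenness rule 11.2%.

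Genes were named in the text as follows. In each held-out list these were the genes meeting the size rule, at most the 3 with the largest difference in share of cells for each direction, and at most 2 others with the highest mean CPM. Per class the 5 markers detected in most cells were named, and per cluster the 10 genes with the highest fold among those detected in at least 50% of its cells. Genes without a symbol were skipped. Some genes that these rules name are not reported here. CDH1, TFAP2A, TPM4, ID1, ID2, the sarcomere genes, the endothelial genes and the genes named within cluster 2 were chosen after their values were seen. The same holds for LAMB1 and JUP. Folds are ratios of mean CPM with 1 CPM added to each and understate differences of low genes. No fold is given against a class with no detecting cell.

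The class comparison was tested on simulated counts for all 13823 genes with the cells' own read totals. The changed genes were drawn only from those detected in an intermediate share of cells. Of 99 genes changed 4-fold, 40.4% met the size rule, and of 101 changed 16-fold, 88.1%, none in the wrong direction. For genes detected in few cells or in nearly all, recovery was not measured. Of 9900 unchanged measured genes 0.879% met it. Here the classes compared were the simulated ones, not ones found by clustering, and each gene varied independently. The rate is therefore no error rate for classes found by clustering. The clustering placed all 89 simulated cells with their own class but split the simulated classes, which had no structure inside them, into 4 clusters, so clusters within a class can arise from the method alone.

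The settings varied, as listed before the data were examined, were scran size factors, DESeq2 size factors, no filter or at least 3000 genes per cell, no filter on low genes, detection at 1 read or 50 CPM, thinning of all cells to 1071047 reads (8 shallower cells left out, 3 of them mesoderm-like, 0 ectoderm-like and 5 unnamed), 500 or 3000 variable genes, held-out lists allowed in the clustering, resolution 0.5 or 2, Ward clustering, the title prefix regressed out, each prefix alone and a pseudocount of 10 CPM. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, statsmodels 0.14.6, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with scran 1.30.0 and DESeq2 1.42.0.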

Results

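Transcripts were counted in 89 single cells of the chick amniogenic somatopleure, the sheet of ectoderm and mesoderm that folds over the embryo to form the amnion. Grafts holding both layers were pooled from more than 15 embryos at embryonic day 1.5 (stage 10), and the question the design poses is which cells and which programmes of expression this tissue holds. The pool is 1 sample, so cells were not treated as replicates and no test was run. Genes are described by a fixed rule of size, and intervals are exact Clopper-Pearson intervals at 95% that cover counting error only. Reads assigned to genes ranged from 328645 to 2381723 per cell, with a median of 1464140. A median of 5580 genes had a read, the lowest cell having 2394. Cell titles carried the prefix X09 (58 cells) or X29 (31 cells), whose meaning the labels do not give, with median reads of 1417672 and 1472912.

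The cells fell into 6 clusters of 25, 19, 15, 12, 10 and 8 cells. Cluster 1 was ectoderm-like and held 28.1% of cells (25 of 89, interval 19.1 to 38.6%), with 24.1% of X09 and 35.5% of X29 cells. Clusters 2 to 5 were named lateral plate mesoderm-like and together held 62.9% (56 of 89, interval 52.03 to 72.9%), with 70.7% of X09 and 48.4% of X29 cells. Cluster 6 stayed unnamed: its 8 cells had a median of 861478 reads and 2660 genes with a read. Mitochondrial genes took 0.155 to 0.767% of reads in 4 of them (3 X09 cells and 1 X29 cell) and 26.3 to 41.4% in the other 4, all X29. The cells of cluster 6 detected from 0 to 8 ectoderm markers and from 0 to 3 mesoderm markers other than VIM. The cell with 0 of both detected 9 endothelial markers. The mesoderm-like share depended on how clusters were named. Clusters 3, 4 and 5 had 5, 4 and 4 leading mesoderm markers, but also 3 leading ectoderm markers each. Cluster 2 had 4 of mesoderm and 3 of endothelium. In each, a second type thus also reached the 3 markers that the rule asks for. The naming rule was chosen after the data were seen, as the last of 5 tried, and left out the cardiomyocyte markers although that list had been fixed beforehand. With that list used, clusters 3 and 4 took the cardiomyocyte name and the mesoderm-like share was 32.6%. Over all ways of naming that were tried it ran from 11.2 to 62.9%, while the ectoderm-like share was 28.1% in each. When X09 cells were clustered alone the mesoderm-like share was 41.4%, with 21 cells in neither class.

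**Figure D1:**
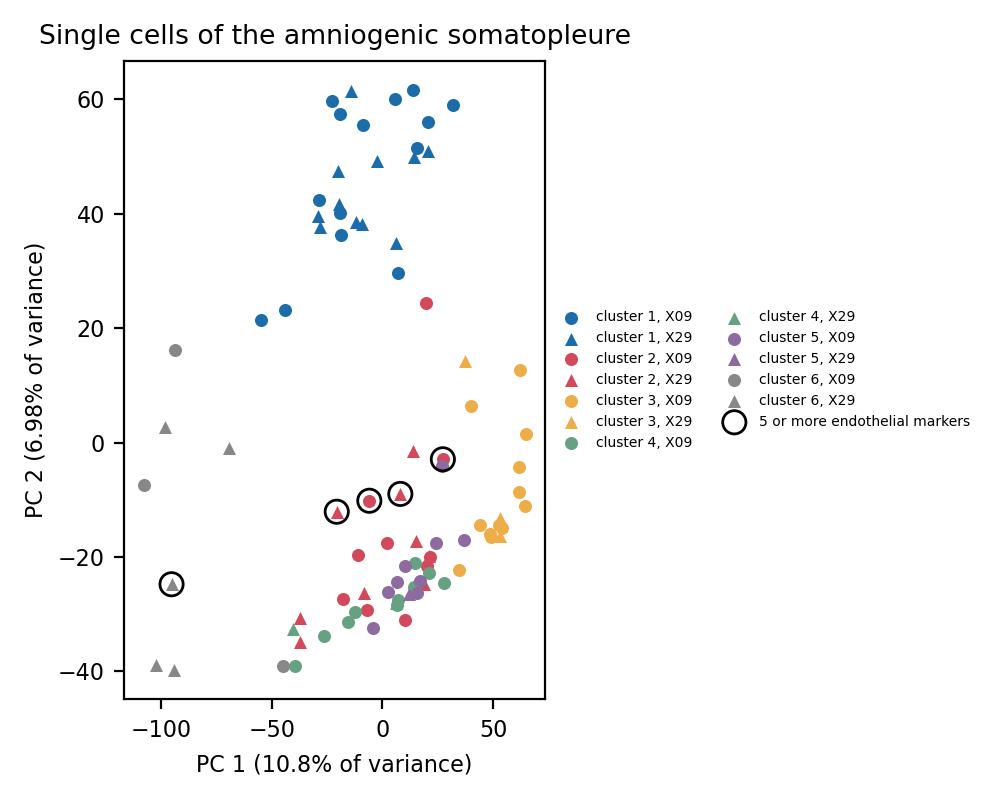
Each point is a cell on the first and second principal components of 1500 variable genes, in units of log2(CPM + 1) with the share of variance on each axis; colours give the 6 clusters, shapes the title prefix, and rings the 5 cells that detected 5 or more endothelial markers. Most ectoderm-like cells lie at the top and most unnamed cells at the left, and 1 cell of cluster 2 lies among the lowest ectoderm-like cells.

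The 5 ectoderm markers detected in most ectoderm-like cells were KRT7, KRT19, EPCAM, KRT18 and GATA2. Each was detected (at least 10 CPM) in all 25 cells. KRT7, KRT18 and KRT19 encode keratins of simple epithelia and EPCAM an epithelial adhesion molecule. CDH1, which encodes E-cadherin, was detected in 80% of them and the surface ectoderm regulator TFAP2A in 92%. The 5 mesoderm markers detected in most mesoderm-like cells were CDH11, PRRX1, VIM, HAND1 and PDGFRA. PRRX1, a homeobox gene of lateral plate mesenchyme, was detected in 100% of the cells of clusters 3, 4 and 5, in 78.9% of cluster 2 and in 16% of the ectoderm-like cells. HAND1 did not part the layers, since it was detected in 100% of the ectoderm-like cells and in 21.1% of cluster 2. The keratins did not part them either: KRT7 was detected in 100% of the cells of each mesoderm-like cluster, and KRT18 and KRT19 in 84.2% or more. At least 3 markers of each layer were found together in 60.7% of cells (54 of 89, interval 49.7 to 70.9%), 67.2% of X09 and 48.4% of X29 cells. Without the 3 keratins and HAND1, an alternative chosen after the data were seen, that share was 11.2%. In the 50 mesoderm-like cells with both sets of markers, KRT7 averaged 5576 CPM and KRT18 812 CPM. Both means were lower in the ectoderm-like cells, at 4975 and 632 CPM. KRT19 went the other way, with 1983 CPM in those 50 cells and 3150 CPM in ectoderm-like cells. Some genes for sarcomere proteins were detected in many cells and others in few. TNNC1 was detected in 92% of the ectoderm-like cells, TNNT2 in 52% of them and in 100% of the cells of clusters 3 to 5, and MYL4 in 80% of cluster 3, 75% of cluster 4 and 28% of cluster 1, while ACTN2 was detected in 2.25% of all cells.

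**Figure D2:**
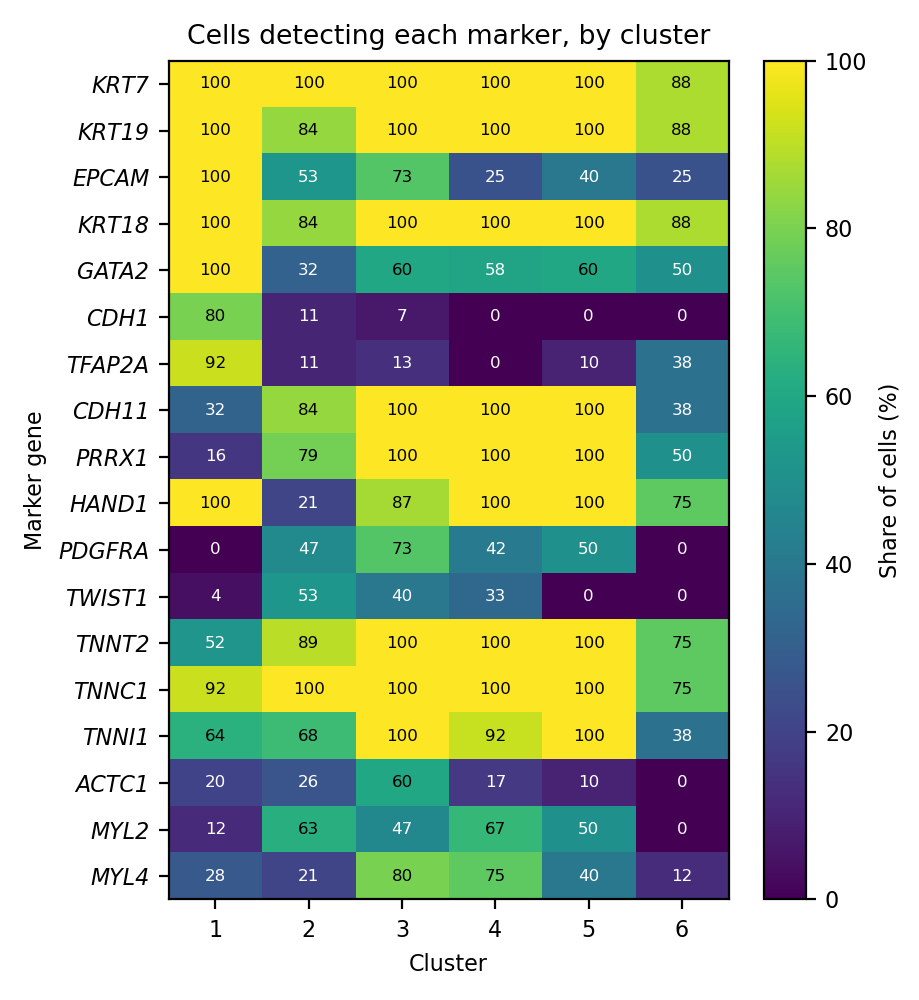
Share of the cells of each cluster (columns, in percent, colour and printed value) that detected each marker gene (rows) at 10 CPM or more. KRT7 was detected in 100% of cells in clusters 1 to 5, CDH1 in 80% of cluster 1, and TNNT2 in 100% of clusters 3, 4 and 5.

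The genes with the highest ratio of mean CPM in a cluster to that in all other cells are given as its description and not as results. Most of them were not among the genes used for clustering, but those of cluster 1 were, except CRYBG2, PLEKHA7 and UPK3B. Cluster 1 was led by VLDLR, ATP8B1, SOSTDC1, ADAMTS18, GCNT1, CRYBG2, UPK1B, PLEKHA7, UPK3B and TXNRD1. Cluster 2 was led by DOCK4, SPOCK1, IRX6, NRP1, FGFRL1, HAPLN3, RFTN2, FKBP1B, RASGRP1 and NCAM1, of which NCAM1 is a fixed neural plate marker and none is a mesoderm marker. Cluster 3 was led by KIF14, NEK2, FANCI, LMBRD2, PEAK1, TICAM1, FOXM1, CIT, FBXO39 and BRIP1, among them genes of mitosis. Cluster 4 was led by TLR15, MFAP5, SUSD1, CLEC3B, AOX1, TNIP2, CRABP-I, VEGFA, PHC1 and EXD2, and cluster 5 by TMEM61, Smad7b, GPM6B, ZC3H7B, CHST2, angiopoietin-2, LRSAM1, ANGPTL1 and CLCN6. Cluster 6 was led by MADPRT1, SAMD11, RRP12, CS, IFI27L1, MGMT, PTRHD1 and OSTF1, of which CS, PTRHD1 and OSTF1 were detected in a lower share of its cells than of the other cells. In 5 cells (5.62%, interval 1.85 to 12.6%) 5 or more of the 11 measured endothelial markers were detected, 4 of these cells lying in cluster 2 and 1 in cluster 6. CDH5, FLI1, KDR and LMO2 were each detected in all 5.

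The mesoderm-like and ectoderm-like cells were then compared over 11 lists of genes that took no part in the clustering. Of 184 listed genes detected in at least 10% of either class, 49 were higher in the mesoderm-like cells and 16 in the ectoderm-like cells by the size rule (a mean at least 2 times higher and a share of cells at least 20 percentage points higher, in the same direction within X09 and X29), and 119 met it in neither direction. HOX genes, which pattern the body axis, stood on the mesodermal side: 11 of 17 measured were higher there and 0 were higher in ectoderm-like cells. HOXB5 was detected in 73.2% of mesoderm-like cells (interval 59.7 to 84.2%; 303 ± 299 CPM, mean ± SD over cells), HOXB4 in 50% and HOXB9 in 39.3%. Clusters 3 to 5 carried these values (94.6, 67.6 and 54.1% of cells), and cluster 2 lay far lower (31.6, 15.8 and 10.5%). In the 15 cluster 2 cells with fewer than 5 endothelial markers the shares were 20, 13.3 and 0%. None of the HOX genes just named was detected in the 25 ectoderm-like cells, which allows a share of up to 12% (3 of 25 cells) or, by the exact interval, 13.7%. HOXA3 was detected in 46.4% of mesoderm-like and 20% of ectoderm-like cells and did not meet the rule. Among 15 measured genes of hedgehog, Notch and retinoid signalling, 3 were higher in mesoderm-like and 2 in ectoderm-like cells. ALDH1A2, whose enzyme makes retinoic acid, was detected in 73.2% of mesoderm-like cells (267 ± 296 CPM) and in 0 of 25 ectoderm-like cells, the Hedgehog effector GLI3 in 92.9% against 48%, and the retinol transporter gene STRA6 in 28.6% against 4%. JAG2, a Notch ligand, was detected in 52% of ectoderm-like and 21.4% of mesoderm-like cells, and DHRS3, a retinaldehyde reductase, in 56% and 26.8%. GLI2 and RARB did not meet the rule, with 102.1 and 82.7 CPM for GLI2 and 77.6 and 88.8 CPM for RARB in mesoderm-like and ectoderm-like cells.

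Most matrix, adhesion and contractile genes met the rule in neither direction. Of 29 measured matrix genes 10 were higher in mesoderm-like cells and 1, COL4A2, in ectoderm-like cells (44% against 16.1% of cells). COL3A1 reached 361 ± 381 CPM in mesoderm-like cells and was detected in 82.1% of them against 8% of ectoderm-like cells, COL1A2 in 73.2% against 0 of 25, and HAPLN1, a linker of hyaluronan and proteoglycans, in 92.9% against 24%. FN1 (257 CPM in mesoderm-like and 643 CPM in ectoderm-like cells) and SPARC (871 and 827 CPM, in the same order) did not meet the rule. FN1 and LAMB1 were detected in more than 80% of both classes, which bars a gene from meeting it. Their mesoderm-like means were 0.401 and 0.472 times their ectoderm-like means. Of 20 measured genes of adhesion and epithelial-mesenchymal transition, 6 were higher in mesoderm-like and 3 in ectoderm-like cells. ZEB1 and ZEB2, repressors of epithelial genes, were detected in 62.5 and 58.9% of mesoderm-like cells and in 0 of 25 ectoderm-like cells, and CDH2, which encodes N-cadherin, in 64.3% against 8%. The tight junction gene CLDN1 was 20.03-fold higher in ectoderm-like cells (2786 ± 973 against 138 ± 511 CPM; 34.05-fold without 1 mesoderm-like cell), and CLDN3 was detected in 92% against 1.79% and ITGA6 in 48% against 23.2%. ITGB1 (393 CPM in mesoderm-like and 245 CPM in ectoderm-like cells) and DSP (767 and 510 CPM) did not meet the rule. JUP, detected in more than 80% of both classes, could not meet it. Its mesoderm-like mean was 0.216 times its ectoderm-like mean. Of 16 contractile genes 3 were higher in mesoderm-like cells and 0 in ectoderm-like cells. ACTA2, smooth muscle actin, was 31.3-fold higher (6000 ± 3401 against 191 ± 513 CPM; 61.9-fold without 1 ectoderm-like cell), CALD1 was detected in 98.2% against 24% and MYH11 in 33.9% against 4%, while ACTB and ACTG1 were detected in 100% of both classes.

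**Figure D3:**
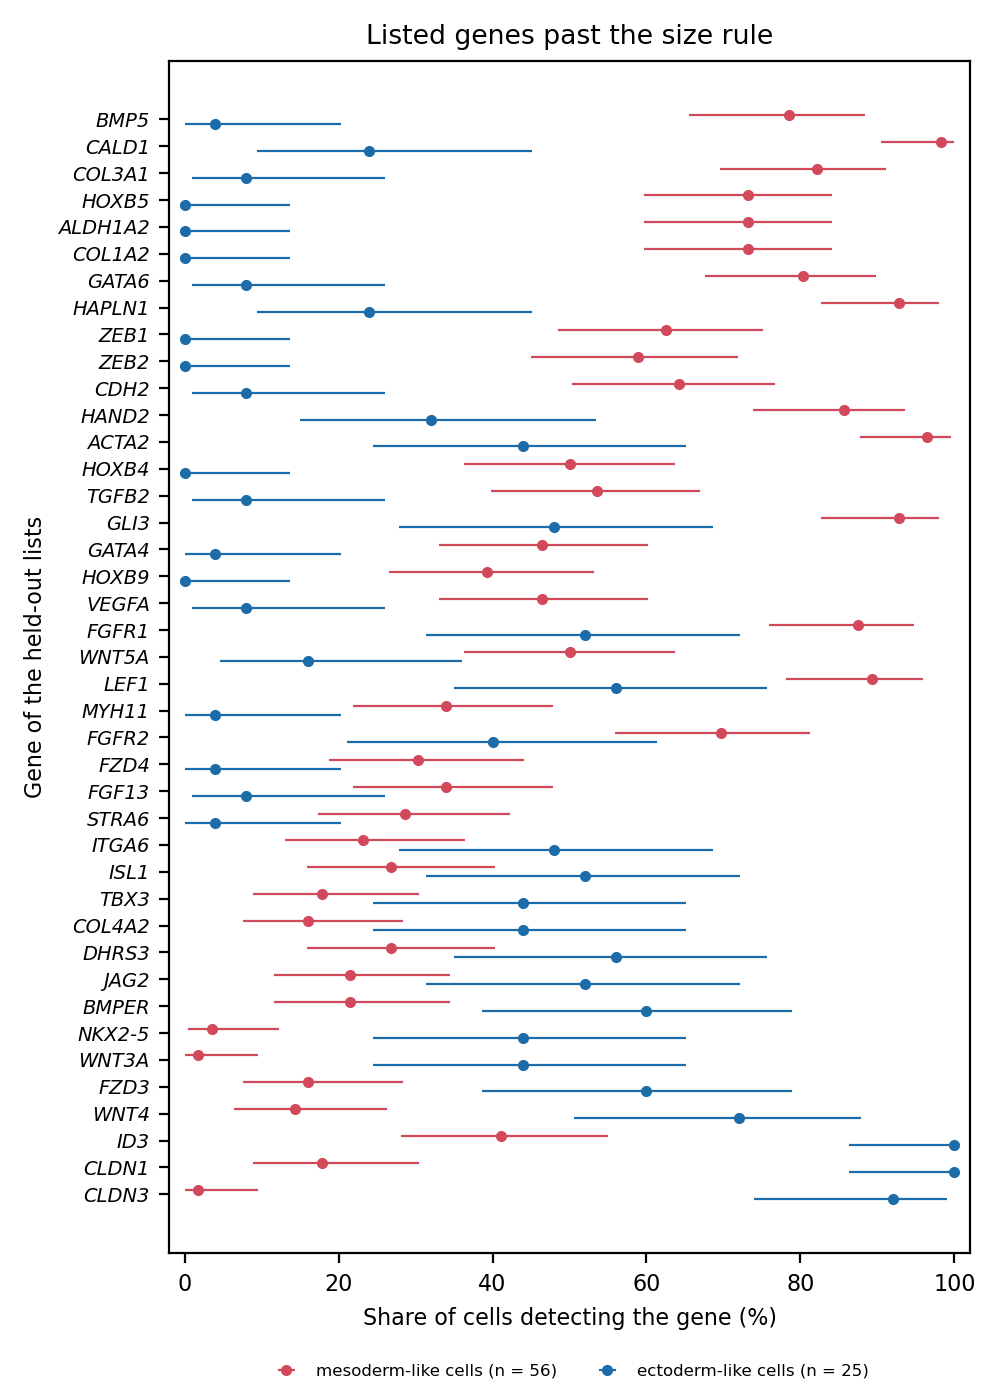
Share of mesoderm-like cells (red, n = 56) and ectoderm-like cells (blue, n = 25) that detected each named gene of the held-out lists meeting the size rule, in percent, with exact 95% intervals as bars. The genes are ordered by the difference between the classes, from BMP5 (78.6% against 4%) to CLDN3 (1.79% against 92%).

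BMP, TGF-beta and WNT genes went in both directions. Of 22 measured genes of BMP and TGF-beta signalling, 2 were higher in mesoderm-like and 2 in ectoderm-like cells. The ligand BMP5 was detected in 78.6% of mesoderm-like cells and in 1 of 25 ectoderm-like cells (207 ± 195 against 2.31 ± 11.5 CPM; 62.8-fold, or 208-fold without that cell) and TGFB2 was detected in 53.6% against 8%. ID3, a target of BMP signalling, was detected in all 25 ectoderm-like cells and in 41.1% of mesoderm-like cells, and BMPER in 60% against 21.4%. BAMBI (1157 CPM in mesoderm-like and 1537 CPM in ectoderm-like cells) and MSX1 (1565 and 528 CPM) did not meet the rule. A gene detected in more than 80% of both classes cannot meet it, and 7 such genes of the 11 lists had means at least 2 times apart. Higher in mesoderm-like cells were 2, MSX1 (2.96-fold) and TPM4 (6.32-fold). For MSX1 this came from clusters 3 to 5 with 2246 CPM, cluster 2 lying below the ectoderm-like cells at 238 CPM. Higher in ectoderm-like cells were 5: ID1 (4.61-fold), ID2 (2.31-fold), and FN1, LAMB1 and JUP given above. Of 23 measured WNT genes, 3 were higher in mesoderm-like cells (WNT5A, FZD4 and LEF1, the last in 89.3% against 56% of cells) and 5 in ectoderm-like cells. WNT4 was detected in 72% of ectoderm-like against 14.3% of mesoderm-like cells, WNT3A in 44% against 1.79%, and the receptor gene FZD3 was 13.3-fold higher. DKK3 and ROR1 did not meet the rule (126 CPM in mesoderm-like and 122 CPM in ectoderm-like cells for DKK3, 153 and 127 CPM for ROR1). Of 10 measured FGF genes 4 were higher in mesoderm-like cells and 0 in ectoderm-like cells, among them the receptors FGFR1 (87.5% against 52%) and FGFR2 (69.6% against 40%) and FGF13 (33.9% against 8%), and FGF12 and FGFR3 did not meet the rule.

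Of 11 measured genes of the heart fields, 6 were higher in mesoderm-like cells and 3 in ectoderm-like cells. GATA6 was detected in 80.4% of mesoderm-like against 8% of ectoderm-like cells, HAND2 in 85.7% against 32% and GATA4 in 46.4% against 4%, all of them regulators of cardiac and lateral plate mesoderm. The GATA4 share came mostly from X09 cells of clusters 3 to 5 (70.97%, against 0% of their 6 X29 cells), and was 21.1% in cluster 2. NKX2-5, a cardiac homeobox gene, was instead detected in 44% of ectoderm-like against 3.57% of mesoderm-like cells, ISL1 in 52% against 26.8% and TBX3 in 44% against 17.9%. For ISL1 this holds against clusters 3 to 5 (10.8%) but not against cluster 2 (57.9%). SRF and TBX20 did not meet the rule. None of the 5 measured genes of the mammalian amnion list met it: S100A10 was detected in 100% of both classes and ANXA1 in 23.2% of mesoderm-like and 28% of ectoderm-like cells. CDX2, also on that list, differed within the mesoderm-like cells. It was detected in 94.6% of clusters 3 to 5 and in 6.67% of the 15 cluster 2 cells with fewer than 5 endothelial markers. Of 16 measured genes of the glycolysis list only VEGFA met the rule, which encodes a growth factor and not a glycolytic enzyme (46.4% of mesoderm-like and 8% of ectoderm-like cells, but 15.8% of cluster 2). GAPDH and LDHB were detected in 100% of both. In the lists counted apart, 1 of 35 measured S-phase genes (SLBP, 68% of ectoderm-like against 42.9% of mesoderm-like cells) and 0 of 41 genes of G2 and mitosis met the rule, PCNA, RRM2, HMGB2 and CDK1 not among them. Of 18 measured genes of dissociation stress, FOS (405 ± 304 against 53.8 ± 84.5 CPM), EGR1 and ATF3 were higher in ectoderm-like cells and HSPB1 in mesoderm-like cells, while HSPA8 and HSP90AA1 were detected in 100% of both. At a detection limit of 50 CPM, 32 list genes were higher in mesoderm-like cells and 17 in ectoderm-like cells, and only 29 and 13 of these were among the 49 and 16 genes above. With clusters 3 and 4 named cardiomyocyte-like, and so left out, the counts were 40 and 19, of which 38 and 15 were among them. Where naming left cluster 5 alone as mesoderm-like the counts were 35 and 17 (29 and 12 among them), with cluster 2 alone 31 and 21 (26 and 14 among them), and in X29 cells alone 40 and 23 (32 and 12 among them). With any 1 cell left out the counts were 47 to 52 and 15 to 17. The calls of FGF13, ITGA6, SLBP, FGFR2 and HSPB1 each ended on leaving out 1 cell, any of 13 cells for FGFR2 and any of 40 for HSPB1.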

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

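The ways of naming clusters, the removal of clusters, of each cell in turn, of cells with endothelial markers or of a mesoderm-like cell with ectoderm markers alone, the marker count without keratins and HAND1, thinning with the classes kept, and the settings for depth and the W-linked gene were chosen after the data were seen; the other alternatives were planned. Of the planned values, 69 stayed within the counting interval of the reported share or within 1.5 times the reported count, and 6 did not. The mesoderm-like share was 47.2% with the title prefix regressed out and 41.4% in X09 cells clustered alone. The ectoderm-like share was 41.9% in X29 cells clustered alone, where 48.4% of cells had markers of both layers. At a detection limit of 50 CPM, 47.2% of cells had markers of both layers and 32 list genes were higher in mesoderm-like cells. Of the values added later, 47 stayed within those bounds and 7 did not. The mesoderm-like share was 32.6% with the cardiomyocyte list used in the rule kept or in the rule by number of leading markers, and 11.2% under the z-score rule or with that list in the evenness rule. These shares follow from how the same 6 clusters were named, the z-score rule naming cluster 2 endothelial. Ward clustering named 4 cells endothelial, all with 5 or more endothelial markers, and regressing out the prefix 13 cells, 4 of them with so many markers. Without the 3 keratins and HAND1, 11.2% of cells had markers of both layers. The W-linked gene was found in 26.97% of cells at 1 read. For the other changes the cause was not tested. Of the share differences of the 46 size-rule genes named in the text, 715 planned values stayed within the counting intervals and 112 moved, and of those added later 584 stayed and 105 moved. These tallies, and the 69 and 47 above, hold runs that repeat the reported classes. All cells passed the filter on cells, so dropping it changed nothing, and the pseudocount does not enter a share. Resolutions 0.5 and 2 and several naming rules not kept gave classes of the same size. The direction turned in 2 runs: the share difference of SLBP, mesoderm-like minus ectoderm-like, was 0.321 percentage points in X09 cells alone, and the share difference of ISL1 was 5.89 percentage points with cluster 2 as the only mesoderm-like cluster. Calls were lost more often: of the 49 genes higher in mesoderm-like cells 29 were still called at 50 CPM, 29 under the z-score rule or with the cardiomyocyte list in the evenness rule, and 32 in X29 cells alone, and of the 16 higher in ectoderm-like cells 11 with DESeq2 size factors. DESeq2 size factors named cluster 6 ectoderm-like, giving an ectoderm-like share of 37.1%. With cluster 2 as the only mesoderm-like cluster, 31 list genes were higher in mesoderm-like cells, 26 of them among the 49. Without cluster 2, 51 list genes were higher in mesoderm-like and 17 in ectoderm-like cells, of which 44 and 16 were among those reported. Naming was judged partly on these same alternatives, so how well the names held under them is not independent evidence. No paired analysis was possible because there is 1 group and no test was run.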

Other observations

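The tests in this part, and the comparison of cluster 2 with clusters 3 to 5, were all chosen after the results were seen. Within the mesoderm-like cells, cluster 2 (15 cells after leaving out 4 with 5 or more endothelial markers) differed from clusters 3 to 5 (37 cells) in 32 of 181 measured list genes, 10 higher in cluster 2 and 22 higher in clusters 3 to 5. Of the 15 cells, 1 had 12 ectoderm markers and no mesoderm marker; without it 31 genes differed, 29 of them among the 32. X29 cells were 7 of the 15 and 6 of the 37. The HOX list gave 9 genes higher in clusters 3 to 5 and 1, HOXA2, higher in cluster 2 (73.3% against 32.4% of cells). HOXB5 was detected in 20% of cluster 2 and 94.6% of clusters 3 to 5, and HOXB9 in 0 of 15 cells against 54.1%. CDX2, a regulator of posterior identity that is also on the mammalian amnion list, was detected in 6.67% against 94.6%. Cluster 2 was higher in ISL1 (60% against 10.8%), ETV5, a target of FGF signalling (80% against 21.6%), VCAN, a matrix proteoglycan (73.3% against 18.9%), and LUM (40% against 2.70%), and clusters 3 to 5 in MSX1 (2246 ± 1050 against 296 ± 362 CPM) and COL3A1 (519 ± 377 against 65.4 ± 95.9 CPM).

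Endothelial cells inside cluster 2 would account for its difference only if it faded without them. Of 33 genes meeting the rule with those cells, 27 (81.8%) still met it without them, although the z-score rule named the whole of cluster 2 endothelial. Median reads were 1494383 in cluster 2 and 1464140 in clusters 3 to 5, so the groups hardly differed in read depth. The group in which a gene was higher was then cut to its cells with fewer reads than the median cell of the other. That left 7 cells of cluster 2 or 22 of clusters 3 to 5, and 29 of the 32 genes (90.6%) kept shares at least 20 percentage points apart. With medians so close this test could change little, and it covers read totals only. Median gene reads per spike-in read were 17.9 in the whole of cluster 2 and 38.6, 11.3 and 18.5 in clusters 3, 4 and 5. Whether captured RNA accounts for the difference was not tested. Simulated classes without inner structure were also split by the clustering, and clusters inside them gave 4 to 6 list genes meeting the rule. In that simulation each gene varied independently, so list genes could not follow clusters formed on other genes. It therefore cannot decide whether a split of cells without distinct groups would give as many genes as cluster 2 did. The labels give no position, so whether cluster 2 comes from another level of the body axis was not tested.

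The difference in HOX genes between mesoderm-like and ectoderm-like cells was weighed against read depth. The ectoderm-like cells were not shallower, with a median of 1545735 reads against 1466001. The 33 mesoderm-like cells with fewer reads than the median ectoderm-like cell still had a median of 6 HOX genes, against 1 (at most 4) in the 25 ectoderm-like cells, a difference of 5. The medians were 8 and 1 in X09 and 4 and 2 in X29 cells, but cluster 2 made up 9 of all 15 mesoderm-like X29 cells and 10 of 41 in X09. Over cells of any depth, cluster 2 had a median of 3 HOX genes in each prefix, and clusters 3 to 5 had 8 in X09 and 6 in X29 cells. Lower read depth of the ectoderm-like cells is argued against by their read totals alone. As they had more reads, the cut to 33 cells could not have spoken for it. Captured RNA was not tested as a cause, median gene reads per spike-in read being 19.5 in mesoderm-like and 19.1 in ectoderm-like cells. Position along the axis, which may differ between the layers sampled, was not tested.

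Markers of both layers in a cell could come from ectodermal RNA in mesoderm-like cells, through doublets or free RNA. That RNA would bring all ectoderm markers in the same ratio. In the 50 mesoderm-like cells with both sets of markers, the 3 keratins stood at a median of 112% of their ectoderm-like level and the 11 other ectoderm markers with at least 20 CPM in ectoderm-like cells at 4.32% (range 0.133 to 11.6%), a ratio of 25.98, which argues against it for the keratins. Below 20 CPM, TP63 stood at 20.5% and DLX6 at 0%. For ectoderm markers other than the keratins, a small amount of RNA from ectoderm-like cells remains open. Doublets remain open for the 10 mesoderm-like cells that kept markers of both layers without keratins and HAND1. They had 1.499 times as many gene reads per spike-in read as the other 46, but 0.809 times within cluster 3, which held 6 of them.

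Gene reads per spike-in read had a median of 38.6 in cluster 3, 19.1 in cluster 1 and 5.56 in cluster 6. In clusters 2, 4 and 5 the medians were 17.9, 11.3 and 18.5. Of 22 W-linked genes fixed beforehand, 1 (SPIN1W) had a row, and it was detected in 16.9% of cells (15 of 89, interval 9.75 to 26.3%) from a pool of embryos of unstated sex.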
